A study of Mus musculus with 24 samples.

How the data were processed

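RNA was sequenced from primary neurons of mouse hippocampus and cortex, grown for 14 days and then given vehicle or BDNF (50 ng/ml) for 1 h. Per the labels, the neurons were wild type (WT) or carried floxed alleles of the gene for GADD34 (Ppp1r15a) and are labelled knockout (KO) in the deposited groups. The series design names a mock virus and a Cre-carrying virus. The sources used here do not say which WT neurons received which, so virus and genotype may be confounded. A further virus delivered a tag for translating ribosome affinity purification (TRAP) under Camk2a sequence. Ribosome-bound RNA was taken on anti-GFP beads from part of the lysate, and RNA of the whole lysate was sequenced beside it. Libraries were made from amplified full-length cDNA by tagmentation.

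The authors deposited 1 table of raw read counts with 23412 gene symbols and 24 library columns. Per the submitters' processing notes, cutadapt, STAR and the mouse genome build mm10 were used. Their versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The table's columns number the libraries of a group 2, 3 and 4 where the titles number them from 1, and libraries are named here by the column number. In the table, 27 gene names had been turned into dates by a spreadsheet, 2 of them occurring 2 times. These stayed in the counts and tests and are not named. No column was left unused.

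The 24 libraries formed 8 groups of 3, by genotype, treatment and fraction. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. Total counts per library ran from 21653732 to 62837379. Replicate pairs differed far beyond counting noise, with a chi-square per degree of freedom of 45.5 or more in each of the 24 pairs, so no library was a copy of another in its group. Across groups this was not computed, and the highest Spearman correlation between any 2 libraries was 0.984.

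Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM normalization, 1 coefficient per group, robust quasi-likelihood F tests, two-sided, and Benjamini-Hochberg adjustment over the genes tested in each comparison. A gene was called at an adjusted p under 0.05. TRAP and total lysate libraries were fitted apart for the effect of BDNF in each genotype, the BDNF by genotype interaction and KO against WT averaged over treatment. All 24 libraries were fitted together for TRAP against total lysate and for the fraction by BDNF interactions. This fit has no term for a lysate that a TRAP and a total library may share. Interactions are differences of log2 fold changes. Group levels are CPM, with library sizes scaled by TMM, given as mean ± SD.

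Before the data were examined, 24 gene lists were fixed, 7 of them cell type markers, along with the tests, the alternatives and the rule for naming genes. The rule names Ppp1r15a first. For each comparison it then takes, among called genes with a mean CPM of at least 5, the 10 with the largest positive and the 10 with the largest negative fold change. For comparisons of 2 groups the libraries of the groups must not overlap. Predicted genes are counted but not named. Where fewer than 5 genes pass, the 5 with the smallest p are taken. The 4 members of each list with the smallest p may be named, and so may every member of the immediate-early, effector, MAPK inhibitor, stress response and eIF2 lists. Genes named in the BDNF effect of 1 genotype may be given in the other. Some genes that the rule allows are not reported here.

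Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 23 lists tested in a comparison. Each test was repeated with the correlation estimated from the data, and with fry, which tests whether the members of a list move on balance in 1 direction and does not compare them with other genes. The mitochondrially encoded list is not analysed here. Members were also counted after adjustment over the list alone.

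Alternatives were edgeR's RLE factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, the replicate number (for TRAP against total, the culture) as a block, subsets of the libraries and leaving out each library in turn. A correction for GC content, the same with the block, and fits without WT vehicle total library 2 were chosen after seeing the data. GC content came from the GENCODE M21 annotation, which matched 21751 symbols, or 92.9% of the table. Whether the numbers pair the libraries was checked by correlating deviations from group means between libraries of the same number. All 3 correlations were above 0.1 for the effect of BDNF in WT TRAP (0.106 to 0.133) and in WT total lysate (0.112 to 0.298), which were therefore read as paired by the data. In the other comparisons at least 1 was not. The values given for the 2 paired comparisons still come from the fit without the block, and the count with the block is given beside them.

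Each fit was tested on simulated data with the libraries' own means and sizes and 100 genes changed per fold size. The changed genes had a mean CPM of at least 5, and libraries were drawn independently, without structure by number or GC content. Recovery therefore does not cover genes below that level, such as Ppp1r15a. The fit recovered 45% of genes changed 2-fold and 94% of genes changed 4-fold for BDNF in WT TRAP, and 39% and 93% in KO TRAP. It recovered 10% and 64% for the interaction in TRAP and 77% and 99% for KO against WT in TRAP. In total lysate it recovered 2% and 57% for BDNF in WT, 7% and 62% in KO, 0% and 9% for the interaction and 32% and 95% for KO against WT. TRAP against total lysate gave 91% and 100%, and the fraction by BDNF interactions gave 2% and 50% in WT and 2% and 37% in KO. False calls made up 0% to 10.6% of the genes called, with the highest share for KO against WT in total lysate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.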

Results

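The study asks whether the translation that BDNF, a neurotrophin, induces in neurons depends on GADD34, a stress-induced subunit that directs protein phosphatase 1 to the initiation factor eIF2. GADD34 is encoded by Ppp1r15a. Ribosome-bound RNA from neurons expressing the Camk2a-driven TRAP tag and RNA of the whole lysate were measured in WT and KO cultures given vehicle or BDNF for 1 h, with 3 libraries in each of the 8 groups. TRAP libraries held 38157125 to 62837379 counts and total lysate libraries 21653732 to 55556100. Counts fell on 15432 to 16212 genes in TRAP libraries. They fell on 16554 to 17334 genes in 11 of the 12 total lysate libraries and on 15422 in WT vehicle total library 2. In that library the ribosomal RNA precursor Rn45s stood at 35943 CPM, against 1109 to 2818 CPM in the other 23 libraries. Its Spearman correlation with the other libraries was 0.917 to 0.935, against 0.955 to 0.984 among the others.

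Ppp1r15a, the targeted gene, lies on chromosome 7 at 45522916 to 45526268 of mm10 on the minus strand, where 12 of its 2937 exonic bases also belong to Tulp2 on the other strand. It was close to the detection limit, with 11 to 43 counts in each of the 24 libraries. In TRAP its level was 0.419 ± 0.247 CPM (SD, n = 3) in WT vehicle, 0.315 ± 0.0546 in WT BDNF, 0.515 ± 0.289 in KO vehicle and 0.560 ± 0.167 in KO BDNF. In total lysate it was 0.859 ± 0.435, 0.682 ± 0.227, 0.598 ± 0.299 and 0.592 ± 0.255 CPM in the same order. KO against WT gave a log2 fold change of 0.56 (SE 0.79, 95% interval -1.13 to 2.25, edgeR adjusted p = 0.766) in TRAP and -0.36 (SE 0.58, -1.61 to 0.90, adjusted p = 1.00) in total lysate. No loss of the transcript in KO libraries was detectable at this depth. The part of the gene that Cre removes is not given in the sources used here, so these counts do not check the genotype labels.

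**Figure D1:**
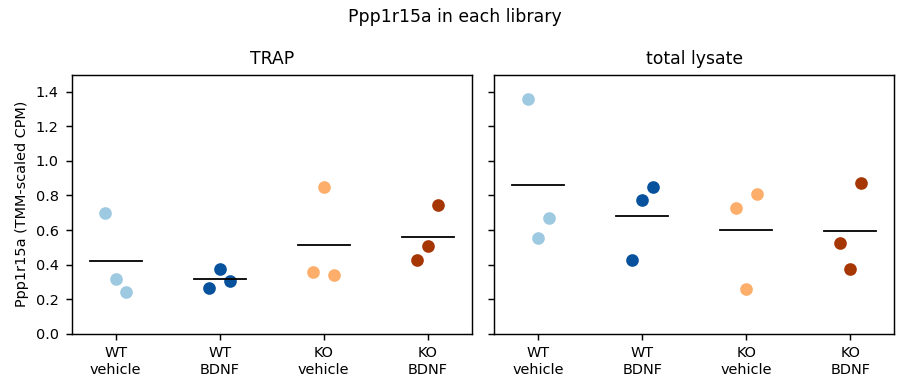
Ppp1r15a in each of the 24 libraries, as TMM-scaled CPM, by group for TRAP and total lysate; points are libraries and bars are means of 3. The 3 KO BDNF libraries lie above the 3 WT BDNF libraries in TRAP, and each other KO group overlaps its WT counterpart.

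The effect of BDNF on ribosome-bound RNA in WT neurons was a rise of immediate-early genes. Arc, which encodes a synaptic protein and is a standard marker of neuronal activity, rose 7.43-fold in TRAP, from 172 ± 45.3 CPM to 1281 ± 213 (SD, n = 3; log2 fold change 2.89, SE 0.23). Arc lies on chromosome 15 at 74669083 to 74672570 of mm10. Of the 23 immediate-early transcription factors, 10 rose, among them Btg2 (2.50, SE 0.31), Egr2 (2.12, SE 0.27), Junb (1.95, SE 0.17), Fos (1.71, SE 0.20) and Npas4 (1.71, SE 0.25). Egr4 rose by 2.05 (SE 0.17), Ier2 by 2.05 (SE 0.23), Fosb by 1.54 (SE 0.22), Nr4a1 by 1.33 (SE 0.21) and Egr1 by 1.31 (SE 0.16). The natriuretic peptide gene Nppa rose by 2.95 (SE 0.31), from 1.33 ± 0.0346 CPM to 10.3 ± 0.679.

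Other genes that rose in WT TRAP were the stress-inducible growth arrest genes Gadd45g (1.87, SE 0.25) and Gadd45b (1.52, SE 0.22), the small GTPase gene Arl4d (1.89, SE 0.33) and the secreted matrix protein gene Cyr61 (1.65, SE 0.23). Dusp1, a phosphatase that switches off MAP kinases, rose by 1.82 (SE 0.24) and was the only called member of the 16 MAPK feedback inhibitors, of which 6 passed when adjusted over the list alone. Of the 23 activity-regulated effectors, 3 rose (Arc, Gadd45b and Gadd45g), and 5 passed adjusted over the list alone. The immediate-early list had a median log2 fold change of 1.16, with 16 members passing adjusted over the list alone (camera adjusted p = 2.05e-42; adjusted p = 7.49e-05 with an estimated correlation). The MAPK inhibitors had a median of 0.50 (camera adjusted p = 2.09e-07; adjusted p = 0.0930 with an estimated correlation) and the effectors of 0.22 (0.000303; adjusted p = 0.306 with an estimated correlation).

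No integrated stress response target (26 tested, median 0.03, camera adjusted p = 0.406) and no eIF2 pathway component (20 tested, median -0.09, camera adjusted p = 0.0706) was called in WT TRAP after BDNF. Astrocyte markers had a median of 0.19 (camera adjusted p = 0.00510; adjusted p = 0.330 with an estimated correlation) and vascular and fibroblast markers of 0.39 (0.0446; adjusted p = 0.206 with an estimated correlation), with 0 members called in either. The p53 targets had a median of 0.21, with Btg2, also an immediate-early gene, as the only called member (0.0201; adjusted p = 0.206 with an estimated correlation). Medians were -0.17 for nuclear-encoded oxidative phosphorylation (0.000896; adjusted p = 0.585 with an estimated correlation), -0.13 for actin cytoskeleton (0.0446; adjusted p = 0.281 with an estimated correlation) and -0.13 for synaptic vesicle and release (0.0253; adjusted p = 0.306 with an estimated correlation), each with 0 members called. In all, edgeR's quasi-likelihood test called 18 of 15665 genes, all higher, with 557 at an unadjusted p under 0.05 and a smallest adjusted p of 4.99e-05. DESeq2 called 39, with 38 higher and 1 lower, and limma voom 21. With the replicate number as a block, edgeR called 27, all higher, with 1238 at an unadjusted p under 0.05. Of the 17 called genes named here, 12 kept their call whichever library was left out, and the other 5 were Arl4d, Nr4a1, Gadd45b, Npas4 and Cyr61, with highest adjusted p across the alternatives of 0.198, 0.123, 0.0804, 0.0661 and 0.0577. Of the 12, Fosb lost its call with a GC correction (1.43, edgeR adjusted p = 0.0544).

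**Figure D2:**
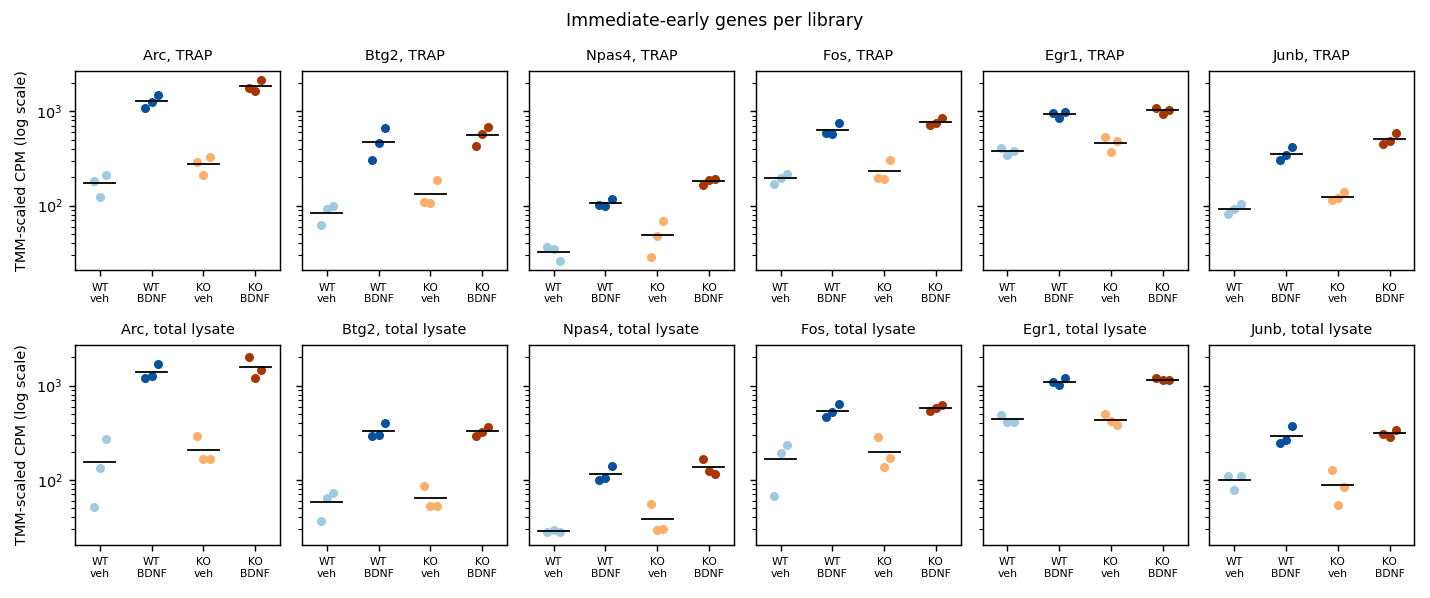
TMM-scaled CPM on a log scale for 6 immediate-early genes in each library, with TRAP above and total lysate below; points are libraries and bars are means of 3. In each panel and genotype the BDNF libraries lie above the vehicle libraries.

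The same comparison in the libraries labelled KO asks how ribosome-bound RNA responded to BDNF in that genotype. Arc rose 6.75-fold in TRAP, from 277 ± 58.4 CPM to 1870 ± 262 (SD, n = 3; log2 fold change 2.75, SE 0.23). Of the 23 immediate-early transcription factors, 11 rose, led by Ier2 (2.34, SE 0.23), Egr2 (2.30, SE 0.27), Egr4 (2.18, SE 0.17), Btg2 (2.07, SE 0.30) and Junb (2.04, SE 0.17). Fosb rose by 1.99 (SE 0.22), Npas4 by 1.90 (SE 0.25), Fos by 1.73 (SE 0.20), Jun by 1.41 (SE 0.24), Nr4a1 by 1.35 (SE 0.21) and Egr1 by 1.15 (SE 0.16). Nppa rose by 2.18 (SE 0.30), Gadd45g by 2.14 (SE 0.25), Arl4d by 2.09 (SE 0.33), Dusp1 by 1.98 (SE 0.24), Gadd45b by 1.72 (SE 0.22) and the kinase gene Pim3 by 1.32 (SE 0.22).

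The immediate-early list had a median of 1.41 in KO TRAP, with 17 members passing adjusted over the list alone (camera adjusted p = 1.06e-36; adjusted p = 0.000130 with an estimated correlation). For the MAPK inhibitors 1 member rose, 7 passed adjusted over the list alone, and the median was 0.56 (7.82e-10; adjusted p = 0.0419 with an estimated correlation). For the effectors 3 rose, 4 passed adjusted over the list alone, and the median was 0.32 (1.63e-06; adjusted p = 0.404 with an estimated correlation). The stress response targets had a median of 0.07 (camera adjusted p = 0.896) and the eIF2 components of -0.05 (0.970), with 0 members called. The quasi-likelihood test of edgeR called 19 genes, all higher, with 807 at an unadjusted p under 0.05 and a smallest adjusted p of 3.89e-05. DESeq2 called 60, with 44 higher and 16 lower, and limma voom 22. Of 18 called genes named here, 13 kept their call whichever library was left out, and the other 5 were Jun, Pim3, Nr4a1, Arl4d and Btg2, with highest adjusted p across the alternatives of 0.281, 0.162, 0.155, 0.145 and 0.0975. Of the 13, with only the 6 libraries compared, edgeR's adjusted p was 0.0652 for Nppa, 0.0511 for Npas4 and 0.0778 for Egr1, and with a GC correction it was 0.0678 for Egr1 (1.01).

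The BDNF by genotype interaction in TRAP asks whether the rise of ribosome-bound RNA depends on the genotype label. It bears on the study's question only in part, since ribosome-bound RNA can also change with the RNA level. Whether the fraction by BDNF interaction differs between genotypes was not tested. The counts of Ppp1r15a did not show its loss in the KO libraries. Of the 20 genes called in either genotype, 17 were called in both, against 0.0218 expected for independent lists. Cyr61 was called in WT alone (1.65 in WT; 1.23, adjusted p = 0.0647 in KO), and Jun (1.16, adjusted p = 0.148 in WT) and Pim3 (1.10, adjusted p = 0.126 in WT) in KO alone. These differences in calls depend on the fit. With the replicate number as a block in edgeR, Jun (adjusted p = 0.00377, range over alternatives 0.000989 to 0.874) and Pim3 (adjusted p = 0.00108, range 0.000918 to 0.863) were called in WT TRAP too, and DESeq2 and limma voom called all 3 genes in both genotypes. The differences between genotypes for the 20 genes ran from -0.77 for Nppa to 0.45 for Fosb on the log2 scale, with a median of 0.17 and 15 of 20 positive. For Arc the difference was -0.14 and for Btg2 -0.43. Each of the 20 95% intervals includes 0. Their lowest end was -1.64, for Nppa, and their highest 1.17, for Arl4d. Others were narrower, such as -0.64 to 0.31 for Egr1 and -0.41 to 0.59 for Junb. Differences within a gene's own interval are not excluded by these libraries.

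Among all genes the smallest interaction p belonged to genes outside the BDNF response, such as Nsmaf (-1.37, SE 0.28), the protocadherin gene Pcdhb22 (-2.10, SE 0.46) and the laminin gene Lama2 (-2.16, SE 0.52), each with an edgeR adjusted p of 1.00. S100a8, a gene of neutrophils with a mean of 1.89 CPM in TRAP, ranked between Pcdhb22 and Lama2 (-3.51, SE 0.80). Its possible carry-over between libraries is taken up below. Interaction medians were 0.09 for the immediate-early list (camera adjusted p = 0.547), -0.02 for the stress response targets (0.779) and 0.19 for the eIF2 components (0.314). By edgeR, 0 of 15665 genes were called, with 471 at an unadjusted p under 0.05. DESeq2 called 9 and limma voom 0. Of the 23 lists 3 were called, and 0 with an estimated correlation, where the smallest adjusted p was 0.677.

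**Figure D3:**
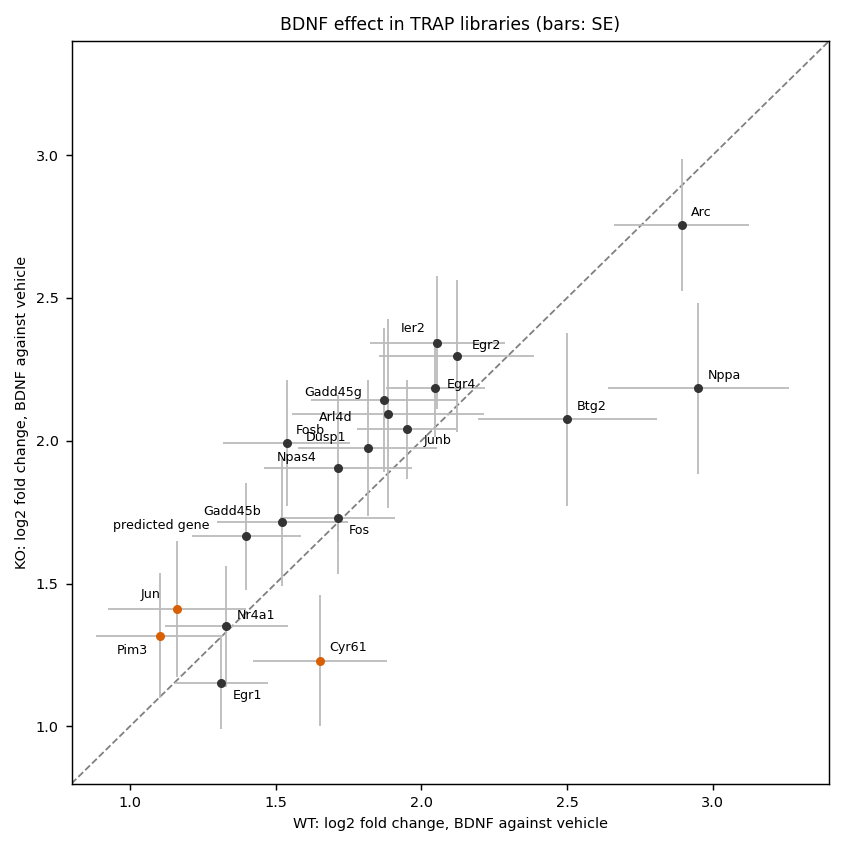
Log2 fold change after BDNF in TRAP for the 20 genes called in at least 1 genotype, WT on the horizontal and KO on the vertical axis; bars are SE, the dashed line marks equal change, and orange points were called in 1 genotype. Differences from the line run from -0.77 to 0.45.

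KO against WT in TRAP, averaged over treatment, asks whether ribosome-bound RNA differs between the genotype labels apart from BDNF. The immediate-early list had a median log2 fold change of 0.43, with 0 members called over all genes and 9, all higher in KO, adjusted over the list alone (camera adjusted p = 2.05e-06; adjusted p = 0.0550 with an estimated correlation). Npas4, a transcription factor induced by neuronal activity, had a difference of 0.68 (SE 0.18), Fosb of 0.61 (SE 0.15), Egr4 of 0.57 (SE 0.12) and Junb of 0.48 (SE 0.12). After correction for GC content these were 0.48, 0.41, 0.09 and 0.11. Among the effectors 2 members, Arc (0.61, SE 0.15) and Gadd45b (0.73, SE 0.16), passed adjusted over the list alone, and after the GC correction these had differences of 0.35 and 0.52.

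Of the 26 integrated stress response targets, 3 passed in KO against WT TRAP adjusted over the list alone, and 0 over all genes (median -0.08, camera adjusted p = 0.276). These were the transcription factor gene Atf4 (-0.48, SE 0.13), Vldlr (-0.67, SE 0.16) and the asparagine synthetase gene Asns (-0.40, SE 0.11), with -0.67, -0.44 and -0.28 after the GC correction. No eIF2 component passed either way (median -0.13, camera adjusted p = 0.313). The smallest p over all genes belonged to Pcna, a DNA replication clamp (-0.77, SE 0.13), Acot9 (-0.81, SE 0.14), Bbip1 (-0.77, SE 0.13), Phyhip (0.66, SE 0.11) and Exosc9 (-0.78, SE 0.14), and edgeR's smallest adjusted p was 0.117. With the GC correction these 5 genes had -0.60, -0.62, -0.53, 0.39 and -0.54. By edgeR 0 of 15665 genes were called, while 2654, or 16.9%, had an unadjusted p under 0.05. With the replicate number as a block, edgeR called 1638 (748 higher and 890 lower in KO), and 302 with the GC correction added. Only 11 of 18 same-number correlations were above 0.1 here, so these libraries were not read as paired. All 18 (0.0559 to 0.167) exceeded the highest correlation between different numbers (0.0149). The choice between 0 and 1638 genes in edgeR thus rests on the 0.1 threshold. DESeq2 called 687, with 257 higher and 430 lower in KO, and limma voom 270, with 79 higher and 191 lower. Fold changes of KO against WT in TRAP followed GC content across genes (Spearman 0.467 over 14639 genes, which are not independent), as did those of BDNF in KO total lysate (0.419), KO TRAP (0.319) and WT TRAP (0.253). After correction 1688 genes of KO against WT in TRAP had an unadjusted p under 0.05.

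In total lysate the effect of BDNF gives the change in all RNA, as a background to TRAP. In WT neurons Btg2 rose by 2.52 (SE 0.32, edgeR adjusted p = 0.0452), from 57.9 ± 19.1 CPM to 332 ± 61.2 (SD, n = 3), as the only gene called. Arc stood at 154 ± 112 and 1386 ± 271 CPM, a log2 fold change of 3.17 with an edgeR adjusted p of 0.129. Egr4 had a fold change of 2.45 (adjusted p = 0.124), Npas4 of 2.02 (0.124) and Fosb of 1.98 (0.134). Nppa, with the largest rise among the genes called in WT TRAP, had -0.41 (95% interval -3.06 to 2.24). In KO neurons 0 genes were called, with values of 2.35 for Btg2 (edgeR adjusted p = 0.0902), 2.90 for Arc (0.138), 1.41 for Egr1 (0.138), 1.88 for Arl4d (0.138), 1.83 for Npas4 and 2.03 for Fosb. For Nppa the KO value was 2.45 (95% interval -0.30 to 5.20).

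The immediate-early list had a median of 1.33 in WT total lysate (1 member rose, 15 passed adjusted over the list alone, camera adjusted p = 7.32e-25; adjusted p = 0.0247 with an estimated correlation) and of 1.26 in KO (0 called, 14 passed adjusted over the list alone, 8.08e-45; adjusted p = 0.00343 with an estimated correlation). For the MAPK inhibitors 4 and 1 members passed adjusted over the list alone, in WT (0.000181; adjusted p = 0.519 with an estimated correlation) and KO (1.47e-08; adjusted p = 0.119 with an estimated correlation). For the effectors 4 and 2 passed adjusted over the list alone, in WT (0.00277; adjusted p = 0.519 with an estimated correlation) and KO (1.36e-07; adjusted p = 0.126 with an estimated correlation). In WT total lysate, camera also placed ribosomal proteins (median -0.37, 2.20e-05), excitatory neuron markers (-0.55, 0.00144), inhibitory neuron markers (-0.41, 0.00208) and postsynaptic density genes (-0.33, 0.00373) lower. Their adjusted p was 0.545, 0.519, 0.519 and 0.519 with an estimated correlation, and 0.956, 0.956, 0.740 and 0.956 without WT vehicle total library 2.

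By edgeR, 639 of 16094 genes in WT and 178 in KO total lysate had an unadjusted p under 0.05 after BDNF. DESeq2 called 15 and 13 genes and limma voom 13 and 18. With the replicate number as a block, edgeR called 1 gene in WT, with 334 at an unadjusted p under 0.05. The call of Btg2 in WT was lost without any 1 of the 3 WT BDNF libraries or WT vehicle total library 3 (edgeR adjusted p up to 0.998 across the alternatives). Without WT vehicle total library 2, 5 genes were called in WT and 12 in KO, and without WT vehicle total library 4, 2 in WT.

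The BDNF by genotype interaction in total lysate had 0 genes called by edgeR, with 200 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom. The difference for Btg2 was -0.17 (95% interval -1.11 to 0.76), and the genes with the smallest p included Supt20 (-1.64, SE 0.46, adjusted p = 1.00). The immediate-early list had a median difference of -0.02 (camera adjusted p = 0.894), and 4 other lists were called, all lost without WT vehicle total library 2 (adjusted p = 0.876) and with an estimated correlation (adjusted p = 0.948). KO against WT in total lysate had 0 genes called by edgeR, with 222 at an unadjusted p under 0.05, against 2 by DESeq2 and 0 by limma voom. The genes with the smallest p there included S100a9, a gene of neutrophils (-2.58, SE 0.55), and Wtip (1.28, SE 0.32), both with an adjusted p of 1.00, and 0 lists were called. The immediate-early list had a median of 0.06 (camera adjusted p = 0.422).

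TRAP against total lysate shows what the purification enriched and depleted. Single genes that were higher in TRAP included the vesicular glutamate transporters Slc17a6 (1.12, SE 0.16) and Slc17a7 (0.85, SE 0.14), the cortical transcription factor Tbr1 (0.97, SE 0.13), the synaptic vesicle protein Syp (0.97, SE 0.12) and the receptor subunit Grin1 (0.76, SE 0.13). Excitatory neuron markers (7 of 23 higher, 7 adjusted over the list alone) and postsynaptic density genes (10 of 35 higher, 11 adjusted over the list alone) lost their call as lists with an estimated correlation (adjusted p = 0.112 and 0.0735). Oligodendrocyte lineage markers were lower, with 15 of 17 called, such as Gpr17 (-1.21, SE 0.13) and Olig1 (-0.95, SE 0.11). The noncoding RNAs Neat1 (-3.02, SE 0.22), Xist (-1.96, SE 0.45) and Snhg11 (-1.77, SE 0.17) were lower in TRAP.

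Other genes with large depletion in TRAP were Neu4 (-2.08), Snx22 (-1.93), Fam216b (-1.91), Pifo (-1.89), the mitotic gene Cenpf (-1.78), Tmem123 (-1.75) and Ybx1 (-1.70), which encodes an RNA-binding protein. The most enriched were Lars2 (1.67, SE 0.28), Zfp97 (1.42, SE 0.48), Pcdhb12 (1.39, SE 0.17), the neuropeptide receptor gene Npy5r (1.30), Tmem132a (1.17), Hsd11b1 (1.16), Tmem59l (1.10), Slit3 (1.10) and the ephrin receptor gene Epha4 (1.09). Zfp97 lost its call without any of 16 of the 24 libraries (adjusted p up to 0.139 by edgeR's quasi-likelihood test). Zfp97, Pcdhb12 and ribosomal protein genes belong to families with near-identical copies, and their counts are uncertain where reads were shared.

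In TRAP against total lysate 5 lists were called with the preset and with the estimated correlation. Oligodendrocyte lineage markers had a median of -1.21 (0 higher and 15 lower of 17, 15 adjusted over the list alone, adjusted p = 0.00229 with an estimated correlation). Cycling and progenitor markers had a median of -0.84 (0 higher and 9 lower of 18, 9 adjusted over the list alone, adjusted p = 0.0162 with an estimated correlation). Synaptic vesicle and release genes, with Sv2b (0.74), had a median of 0.39 (14 higher and 0 lower of 30, 17 adjusted over the list alone, adjusted p = 0.00110 with an estimated correlation). Translation factors, with Eif3c (0.50), had a median of 0.14 (7 higher and 1 lower of 37, 14 adjusted over the list alone, adjusted p = 0.00437 with an estimated correlation). Actin cytoskeleton genes had a median of 0.12 with members both ways, such as Kalrn (0.92) and Tmsb4x (-0.85) (8 higher and 7 lower of 48, 17 adjusted over the list alone, adjusted p = 0.0363 with an estimated correlation).

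A further 12 lists were called with the preset correlation alone in TRAP against total lysate. The higher ones were activity-regulated effectors, with Ptgs2 (1.08) (7 of 23 higher, 11 adjusted over the list alone, adjusted p = 0.0783 with an estimated correlation), ER chaperones, with Hspa5 (0.57) (8 higher and 1 lower of 21, 10 adjusted over the list alone, 0.0609), and cholesterol synthesis (9 higher and 1 lower of 24, 12 adjusted over the list alone, 0.0687). Immediate-early transcription factors, with Btg2 (0.88) (5 of 23 higher, 5 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation), and the excitatory neuron and postsynaptic density lists given above were also higher. Oxidative phosphorylation genes had 17 higher and 7 lower of 52 (29 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation).

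The lower lists of this kind were ribosomal proteins, with Rps12 (-1.25) and Rps28 (-1.22) (3 higher and 22 lower of 78, 27 adjusted over the list alone, adjusted p = 0.521 with an estimated correlation), inhibitory neuron markers, with Cort (-1.01) and Lhx6 (-0.58) (7 of 23 lower, 10 adjusted over the list alone, 0.159), and microglia and macrophage markers, with C1qb (-0.93) (6 of 18 lower, 6 adjusted over the list alone, 0.382). Without WT vehicle total library 2 these lists had a camera adjusted p of 0.324, 0.101 and 0.101. Interferon response genes (5 of 27 lower, 5 adjusted over the list alone, adjusted p = 0.0658 with an estimated correlation) and vascular and fibroblast markers (4 of 17 lower, 4 adjusted over the list alone, 0.159) were lower as well.

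The remaining 6 lists were not called in TRAP against total lysate. Astrocyte markers had 4 of 20 members lower, among them S100b (-0.76) and Aqp4 (-0.49) (4 adjusted over the list alone, camera adjusted p = 0.241), and histone genes 4 of 9 lower (4 adjusted over the list alone, 0.0757). Stress response targets had 3 higher and 3 lower of 26, such as Asns (0.66), Gars (0.50), Nupr1 (-1.10) and Atf4 (-0.39) (6 adjusted over the list alone, 0.384). The p53 targets had 2 higher and 2 lower of 20 (4 adjusted over the list alone, 0.454), the eIF2 components 1 higher of 20, Eif2b3 (0.60) (1 adjusted over the list alone, 0.228), and the MAPK inhibitors 1 lower of 16 (0 adjusted over the list alone, 0.146). By edgeR, 2980 of 16599 genes were called, 1264 higher and 1716 lower, with 5298 at an unadjusted p under 0.05. The count was 6043 with limma voom and 137 with vehicle libraries alone. With a block on culture, edgeR called 3383 genes, 1706 higher and 1677 lower, and 2647 of these were among the 2980. The share of higher calls was 42.4% as reported and 50.4% with that block. With the block and a GC correction it was 56.4% (2346 higher and 1810 lower).

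**Figure D4:**
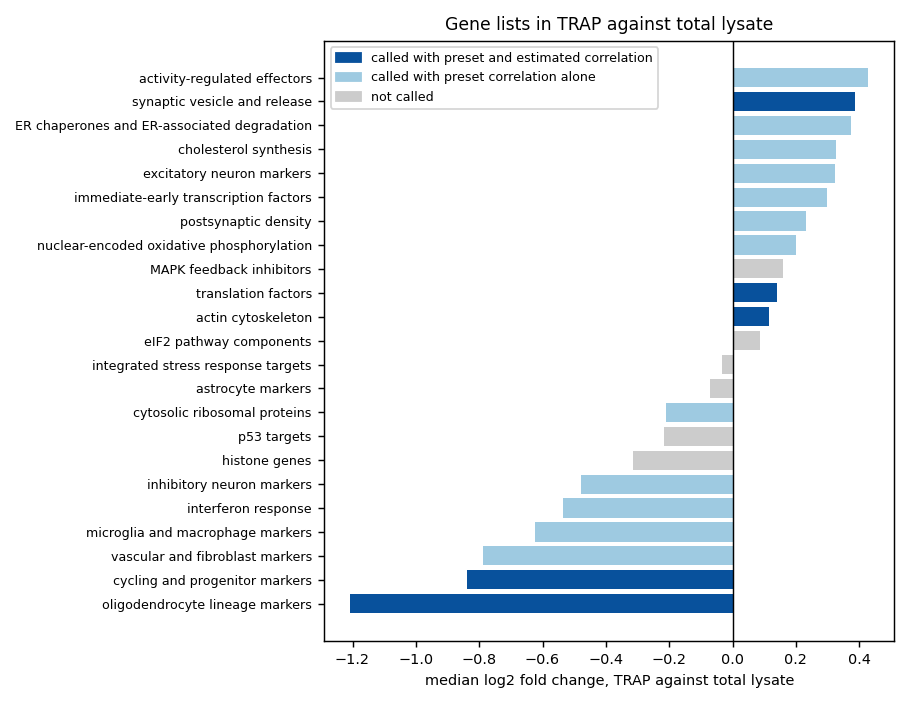
Median log2 fold change of TRAP against total lysate for the 23 lists tested; colours show whether camera called a list with the preset and the estimated correlation, with the preset one alone, or not. Oligodendrocyte lineage markers have the lowest median, -1.21.

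The fraction by BDNF interactions ask whether ribosome-bound RNA changed by more or less than lysate RNA, though TRAP covers tagged neurons and the lysate all cells. The immediate-early list differed between fractions by a median of -0.02 in WT (camera adjusted p = 0.788) and 0.01 in KO (0.856). The effectors had medians of 0.01 (0.788) and -0.07 (0.902), and the stress response targets of 0.06 (0.920) and -0.04 (0.856). Among genes with the smallest p were Lrrc1 (1.89, SE 0.53) in WT and Rnf185 (1.19, SE 0.32) and Bend4 (-1.93, SE 0.52) in KO, each with an edgeR adjusted p of 1.00. By edgeR, 0 genes were called in WT, with 694 at an unadjusted p under 0.05, and 0 in KO, with 359. DESeq2 called 10 and 9 genes and limma voom 0 and 0.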

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

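The GC content test, the splits balanced by number and the values without WT vehicle total library 2 were chosen only after the results were seen, and the rule for judging the GC content test was made stricter after its value was seen, which turned GC content as the whole cause from argued against to undecided. Beyond the genes, the effect of BDNF differed between genotypes or fractions for several gene lists, by camera's test of the interaction. None of these differences held with an estimated correlation.

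In TRAP, the interaction with genotype was lower in KO for astrocyte markers (median -0.37, camera adjusted p = 0.00278; adjusted p = 0.677 with an estimated correlation) and for ER chaperones and ER-associated degradation (-0.25, 0.0332; adjusted p = 0.677 with an estimated correlation). It was higher in KO for nuclear-encoded oxidative phosphorylation (0.18, 0.0279; adjusted p = 0.742 with an estimated correlation). Of 100 splits of the 12 TRAP libraries, 51 called as many lists, so chance cannot be excluded (3 lists in the real split, 7 in the highest other).

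In total lysate, the interaction with genotype was higher in KO for cytosolic ribosomal proteins (median 0.30, camera adjusted p = 0.00750), excitatory neuron markers (0.50, 0.00798), inhibitory neuron markers (0.60, 0.00798) and postsynaptic density genes (0.39, 0.00798). With an estimated correlation the adjusted p was 0.948 for each, and without WT vehicle total library 2 it was 0.876 for each. Of 100 splits 45 called as many lists, so chance cannot be excluded (4 in the real split, 8 in the highest other). In WT, the effect of BDNF was higher in TRAP than in total lysate for ribosomal proteins (0.34, camera adjusted p = 0.00870), postsynaptic density genes (0.27, 0.0104) and inhibitory neuron markers (0.44, 0.0231). With an estimated correlation these had an adjusted p of 0.897, 0.782 and 0.769, and without WT vehicle total library 2 of 0.474, 0.966 and 0.579. Of 50 splits 42 called as many lists, so chance cannot be excluded (3 in the real split, 8 in the highest other).

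WT vehicle total library 2, on which those total lysate lists rest, had 15422 genes with counts, a TMM factor of 0.772 against 0.892 to 1.14 in the other 23, and Rn45s at 35943 CPM. Lower depth and the counts taken by Rn45s were argued against as the whole cause: with Rn45s removed and thinned to the same total, the other 11 total lysate libraries kept 16255 to 16976 genes, against 15421 here. A loss of molecules before amplification may have occurred, since 7 genes were at 0 counts here and at 10 CPM or more in both other libraries of the group, against 0 in each of the other 23 libraries, but 7 genes are too few to decide it. No biological explanation was tested, since the design gives none for a single library.

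KO against WT in TRAP had 2654 genes at an unadjusted p under 0.05 with 0 called by edgeR. GC content may account for part of it: a correction lowered the share at an unadjusted p under 0.05 from 16.9% to 10.8%. Of 100 splits with the same correction, 5 reached that share, the real one included (highest other 17.2%). Whether any excess remains was thus undecided under that rule. Lysate RNA carried over in the purification was undecided too, since the change in vehicle TRAP correlated with TRAP minus total in the BDNF libraries at 0.0651 across 11438 genes, which are not independent, and from -0.00256 to 0.137 with 1 of 18 libraries left out. Of 100 splits of the 12 libraries, drawn without regard to number, 5 with the real one had as many genes at an unadjusted p under 0.05 (2654 in the real split, 4303 in the highest other). By these splits chance cannot be excluded. The highest called 1187 genes with 4 libraries numbered 2 and 2 numbered 3 on 1 side, which points to a structure of the samples by number. The 4 other splits as large were all unbalanced by number, and among the 23 others with 2 libraries of each number on each side the highest had 1560 (1149 with the GC correction, against 1688 in the real split). An effect of the genotype or of the virus stays open, as untested.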

How the results depend on the processing

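The GC correction, alone or with the block, and each setting without WT vehicle total library 2 other than the planned leaving out of each library in turn, were chosen after the data were seen. Where a value moved, the cause was not tested unless stated. Within 1.5 times of the reported count stayed all 11 gene counts under RLE factors, without a filter and with the filter of 1 CPM. Under RLE all 128 gene results kept their direction and side of the threshold. Of the 17 called genes followed under the naming rule in WT TRAP, 11 kept their call in every alternative, as did 10 of 18 in KO TRAP, 0 of 1 in WT total lysate and 19 of 52 in TRAP against total lysate, where vehicle libraries alone, with fewer samples, ended 33. Depth limits Ppp1r15a, at 11 to 43 counts per library.

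DESeq2 called 39 genes for BDNF in WT TRAP, 60 in KO TRAP, 9 for the interaction in TRAP, 687 for KO against WT in TRAP, 15 for BDNF in WT total lysate, 13 in KO total lysate, 2 for KO against WT in total lysate, and 10 and 9 for the fraction by BDNF interactions in WT and KO. Limma voom called 270 for KO against WT in TRAP, 13 and 18 for BDNF in WT and KO total lysate and 6043 for TRAP against total lysate, and turned Ppp1r15a in KO against WT total lysate to 0.033. With GC correction 5 and 4 genes were called for BDNF in WT and KO total lysate. With only the 6 libraries compared these were 0 and 4, and with vehicle libraries alone TRAP against total lysate had 137.

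The replicate number as a block called 35 genes for BDNF in KO TRAP (31 higher and 4 lower), 1638 for KO against WT in TRAP (748 higher and 890 lower) and 1 for BDNF in KO total lysate. The block with GC correction called 32, 302 and 2 for these and 3 for BDNF in WT total lysate. The block without WT vehicle total library 2 called 9 and 22 for BDNF in WT and KO total lysate. The block moved the lists called to 5 and 1 for the fraction by BDNF interactions in WT and KO, and it changed no other count by over 1.5 times. Outside the paired comparisons the labels tie same-numbered libraries by number alone. Correlations of deviations between them went down to -0.0522 with all 24 libraries. For KO against WT in TRAP they ran from 0.0559 to 0.167 (highest for different numbers 0.0149), 11 of 18 above 0.1. As a hint from the data, 12 of 12 TRAP and 11 of 12 total lysate libraries correlated best with their own number. The genes Ddx3y and Eif2s3y were lowest in library 2 in each of the 8 groups. The libraries numbered 2 thus shared a trait across groups, whose cause was not tested.

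Leaving out each library in turn gave 13 to 17 genes for BDNF in WT TRAP, 14 to 19 in KO TRAP, 0 to 5 in WT total lysate, 0 to 12 in KO total lysate and 2412 to 4418 in TRAP against total lysate. The 5 and the 12 came without WT vehicle total library 2. Calls were lost in WT TRAP for Arl4d (without any library but BDNF 3), Nr4a1 (BDNF 3 or 4, vehicle 2 or 3), Gadd45b (BDNF 3, vehicle 2 or 3), Npas4 (vehicle 3 or 4) and Cyr61 (vehicle 2 or 3). In KO TRAP they were lost for Pim3 (any but BDNF 2), Jun (BDNF 2 or 3, vehicle 3 or 4), Nr4a1 (BDNF 3 or 4, vehicle 2 or 3), Arl4d (BDNF 2, vehicle 3 or 4) and Btg2 (vehicle 2 or 3). The other 6 gene counts stayed at 0.

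With an estimated correlation the lists called were 1 for BDNF in WT TRAP, 2 in KO TRAP, 0 for the interaction in TRAP, 0 for KO against WT in TRAP, 1 and 1 for BDNF in WT and KO total lysate, 0 for the interaction in total lysate, 5 for TRAP against total lysate and 0 for the fraction by BDNF interaction in WT. By fry they were 1, 2, 0, 1, 1, 1, 0, 18 and 0. Without WT vehicle total library 2, lists called were 4 for BDNF in WT total lysate, 0 for the interaction and 2 for KO against WT in total lysate. The direction turned there for ribosomal proteins (adjusted p = 0.956) and postsynaptic density genes (0.956) after BDNF in WT total lysate, and for ribosomal proteins in the interaction in total lysate (0.876) and between fractions in WT (0.474).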

Other observations

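The test of exchanged labels and the test by number of the 5 neutrophil genes seen first were chosen only after the result was seen, and the rule for judging carry-over and shared numbers on the other neutrophil genes was made stricter after their values were seen. The medians met the bounds set before, and the change turned carry-over from supported, and shared numbers from argued against, to undecided. In total lysate, as in TRAP, BDNF left the stress response and eIF2 lists uncalled. Integrated stress response targets had a median log2 fold change of 0.08 in WT total lysate (camera adjusted p = 0.851) and 0.08 in KO (0.819), and eIF2 pathway components of 0.19 (0.547) and -0.06 (0.872), each with 0 members called. Across genes, which are not independent replicates, the effects of BDNF in WT and KO correlated at a Pearson r of 0.222 in TRAP (11157 genes) and 0.165 in total lysate (11662 genes), the libraries of the effects being separate.

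Other splits of the libraries gave the following counts of called genes. For TRAP against total lysate chance can be excluded (2980 genes in the real split, 0 in the highest other of 50 splits). For its lists another split called as many (17 in the real split, 17 in the highest other), and chance is excluded only in that the share, 2 of 50 splits with the real one, is under 0.05. The 10 splits of 3 against 3 are too few for a share under 0.05. They gave 18 genes in the real split and 0 in the highest other for BDNF in WT TRAP, 19 and 0 in KO TRAP, 1 and 0 in WT total lysate, and 0 and 0 in KO total lysate. For lists they gave 9 and 7, 3 and 9, 7 and 9, and 3 and 9 in the same order. In WT, where the numbers pair the libraries, 4 of the 10 splits part all 3 pairs, and the highest other of these called 6 lists in TRAP and 6 in total lysate.

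Where the real split called 0, every split calls as many, so the splits decide nothing. This holds for the counts of genes in the interaction in TRAP (0 in the real split, 3 in the highest other), KO against WT in TRAP (0 and 1187), the interaction in total lysate (0 and 0), KO against WT in total lysate (0 and 0), and the fraction by BDNF interactions in WT (0 and 1) and KO (0 and 5), with 100 splits each for the former 4 and 50 for the others. It also holds for the lists of KO against WT in total lysate (0 and 7) and the fraction by BDNF interaction in KO (0 and 10). For the lists of KO against WT in TRAP chance cannot be excluded (1 and 7, with 86 of 100 splits as large).

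Genes made by neutrophils, singled out after their values were seen, varied by the library's place in the table or by group. For S100a8 (mean 1.99 CPM), S100a9, Ngp (1.10 CPM), Camp and Mpo the median R2 was 0.902 by column triplet and 0.868 by group. It was higher by triplet in 3 of 5. Triplet and group differ only where the KO vehicle and KO BDNF total libraries numbered 4 sit in each other's place. The 5 genes did not share 1 pattern. In KO TRAP, Mpo was higher with BDNF (1.127 to 1.526 CPM, against 0.08378 to 0.2428 with vehicle). S100a8 was higher there with vehicle (2.986 to 3.225 CPM, against 0.6236 to 1.289 with BDNF). Carry-over from a neighbouring library was undecided, since for 4 neutrophil genes not looked at before the median R2 was 0.661 by triplet, 0.631 by group and 0.256 by number, higher by triplet than by group in 4 of 4 but than by number in 2 of 4, and the order in the table need not be that of processing. Other unseen genes had fewer counts and were left out. They went both ways, such as Elane (0.858 by triplet and 0.873 by group) and Retnlg (0.801 and 0.746). Neutrophils in cultures that share a number stay open too: for the 5 genes seen first the median R2 by number was 0.0168, which decides nothing, since each triplet holds the numbers 2, 3 and 4 and these genes were singled out for varying by triplet. An exchange of the labels of the KO total libraries numbered 4 was argued against, since the immediate-early transcription factors were higher in the library labelled BDNF by a mean log2 difference of 0.816 (SD 0.74), in 19 of 23 genes, against 1.22 to 1.74 in the other 5 pairs.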
